A study of Sparus aurata with 30 samples.

How the data were processed

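RNA was sequenced from head kidney, intestine and liver of gilthead sea bream (Sparus aurata), a farmed marine fish. The fish were fed a control diet or a diet with brewer's spent dry yeast (SDY), the yeast recovered after brewing. Per the series' design text, SDY made up 30% of the test diet and stood in for fish meal (10%) and for protein from plants (31.4%). Each tissue and diet had 5 libraries, 30 in all. Per the labels' protocols, RNA was taken with TRIzol from 5 specimens picked at random, and libraries were made with a directional kit after poly(A) selection. The labels do not say how the specimens were spread over tanks, so p-values measure the spread between specimens and a tank effect stays within the diet contrast. Same-numbered libraries of different tissues are not said to come from the same fish.

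The deposited values are raw counts of reads per gene, made by the authors with featureCounts 1.5.3, per the file headers. Per the file headers, features of type mRNA were summed by gene on the annotation of assembly fSpaAur1.1. The option -O was set, so a read over overlapping genes was counted for each of them, and no strand option and no paired-end option was set. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.4.4, checked with FastQC and aligned with HISAT2 2.1.0, and DESeq2 was used. Among the 25722 genes, 15.3% have a span that overlaps another gene and 11.8% overlap a gene on the other strand. Counts of such genes are uncertain, because reads of a gene and of its antisense partner could not be told apart. Paralogs with near-identical sequence, common in fish, may also have shared or lost reads.

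Of the 25722 gene identifiers, 10196 were symbols and 15526 were LOC identifiers with no name. A RefSeq gene table of the same assembly matched 18022 identifiers. It held no gene descriptions, so genes without a symbol belong to no list, and coordinates were taken from the files.

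Library totals ran from 926 counts in head kidney control replicate 1 to 20580440. The other 29 libraries held at least 9276705 counts, with a median of 17232375. All files and libraries were used, and 0 columns were left unmapped. No pair of libraries within a group was a duplicate, since the chi-square per gene between replicates was at least 22.4. Head kidney control replicate 1 was left out of these pairs, and libraries of different groups were not compared in this way. Counting intervals cover counting error only, because reads without molecular identifiers are not independent molecules.

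Each tissue was tested alone with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, libraries were scaled by TMM, and the quasi-likelihood test compared SDY with control, 5 libraries against 5. P-values were adjusted by the Benjamini-Hochberg method over all genes tested in a tissue, with a threshold of 0.05. Differences of the diet effect between tissues were contrasts in one edgeR fit of all 30 libraries with 6 group means. Standard errors (SE) were taken from the quasi-likelihood F statistic. Values in CPM, the field's unit for counts relative to library size, are TMM-scaled within the tissue for single genes. They are relative to the plain library total for marker lists, and for the renal genes and averaged-effect genes of the closing section.

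There were 41 gene lists, fixed before the data were examined and matched by symbol. Those with at least 5 tested members were tested with camera in limma 3.58.1 on voom log2 CPM, with a preset correlation of 0.01. This gave 117 tests over the 3 tissues, adjusted together. Camera compares a list with the other genes. Beside it stand camera with a correlation estimated per list, and fry, which tests whether the members of a list move on balance one way. Per-gene counts within a list are given over all genes and adjusted over the list alone.

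Named genes followed a rule fixed before the data were examined. Where a tissue had fewer than 10 genes past the threshold, the rule took those with a name and the 5 named genes with the smallest p. It added the 2 members with the smallest p of each list that passed camera with fewer than 2 members past the threshold. For each pair of tissues it took the 5 named genes with the smallest p. Genes named outside the rule were chosen after their values were seen. They are star, hsd3b1, cps1 and LOC115584268 in head kidney, and gadd45b, fosl1, fosl2, myc, ier2, otc, nlrc5 and cd83 in liver. They also include the renal genes cdh16, pax8 and lrp2, the ATF4 targets asns, wars1 and yars1, and the genes of the averaged effect.

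Tissue shares were estimated by fitting each library as a mixture of the pooled profiles of the 3 tissues. The profiles left out the library itself and head kidney control replicates 1 and 3. The fit recovered a mixture simulated from the same profiles. That simulation had no spread between libraries and no further tissue, so it checked the computation only. The tests were checked on simulated data with the real library sizes and 200 changed genes. edgeR recovered 70% of 4-fold and 16% of 2-fold changes in head kidney, 82% and 23% in intestine, and 88% and 43% in liver. Its false calls were 5 of 91, 8 of 113 and 10 of 141. DESeq2 1.42.0 made 6 false calls of 63 in head kidney, 37 of 174 in intestine and 45 of 206 in liver. Without head kidney control replicates 1 and 3, edgeR recovered 86% of 4-fold and 46% of 2-fold changes with 8 false calls of 140, and DESeq2 made 79 false calls of 234. Camera found a list shifted by 0.5 log2 units in each comparison, with 0 other lists past the threshold; genes were simulated as independent, which favours camera.

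Alternatives fixed before the data were examined were DESeq2 size factors (RLE), the DESeq2 Wald test, no filter on low counts, one fit of all 30 libraries, and voom with sample quality weights. Others were a replicate block, only the 20 libraries of a pair of tissues, a filter at a mean log2 CPM of 1 for lists, and leaving out each library in turn. After the data were seen, fits without head kidney control replicates 1 and 3, and an effect averaged over the 3 tissues, were added. Chance was checked by other splits of the libraries, with 100 drawn per tissue for edgeR and the lists, 30 for DESeq2 and 60 for differences between tissues; the 56 splits of 8 head kidney libraries were all run with edgeR. The number for DESeq2 was set by computing time.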

Results

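Transcript counts were compared between sea bream fed a control diet and sea bream fed brewer's spent dry yeast (SDY) at 30% inclusion. Head kidney, a blood-forming and immune organ of fish, intestine and liver were each sampled with 5 libraries per diet. The series' title puts the question as one of immunity. Of the 30 libraries, 29 held between 9276705 and 20580440 counts, with the lowest in liver SDY replicate 3. Head kidney control replicate 1 held 926 counts on 626 genes.

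A mixture fit over all genes gave 28 of 30 libraries their labelled tissue as the largest share, at no less than 0.828 (intestine control replicate 4). Head kidney control replicate 3 was fitted as 0.469 head kidney, 0.503 liver and 0.028 intestine, though the fit allowed these 3 tissues only. Its hepatocyte list averaged 1310 CPM, against at most 7.76 CPM in the other head kidney libraries and 2560 ± 185 CPM (SD, n = 5) in control livers. Its exocrine pancreas list, digestive enzymes made by pancreatic tissue, averaged 228 CPM. In liver that list averaged 1780 ± 695 CPM in controls and 2260 ± 1080 CPM under SDY (SD, n = 5 each). Head kidney control replicate 1 was fitted as intestine with a share of 1 (95% bootstrap interval 0.998 to 1). Its brush border list, genes of the absorptive intestinal surface, averaged 765 CPM, near the 736 ± 262 CPM of control intestine. Both libraries lie in the same group, so the head kidney counts, lists and leading genes are also given without them, a choice made after seeing the data.

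**Figure D1:**
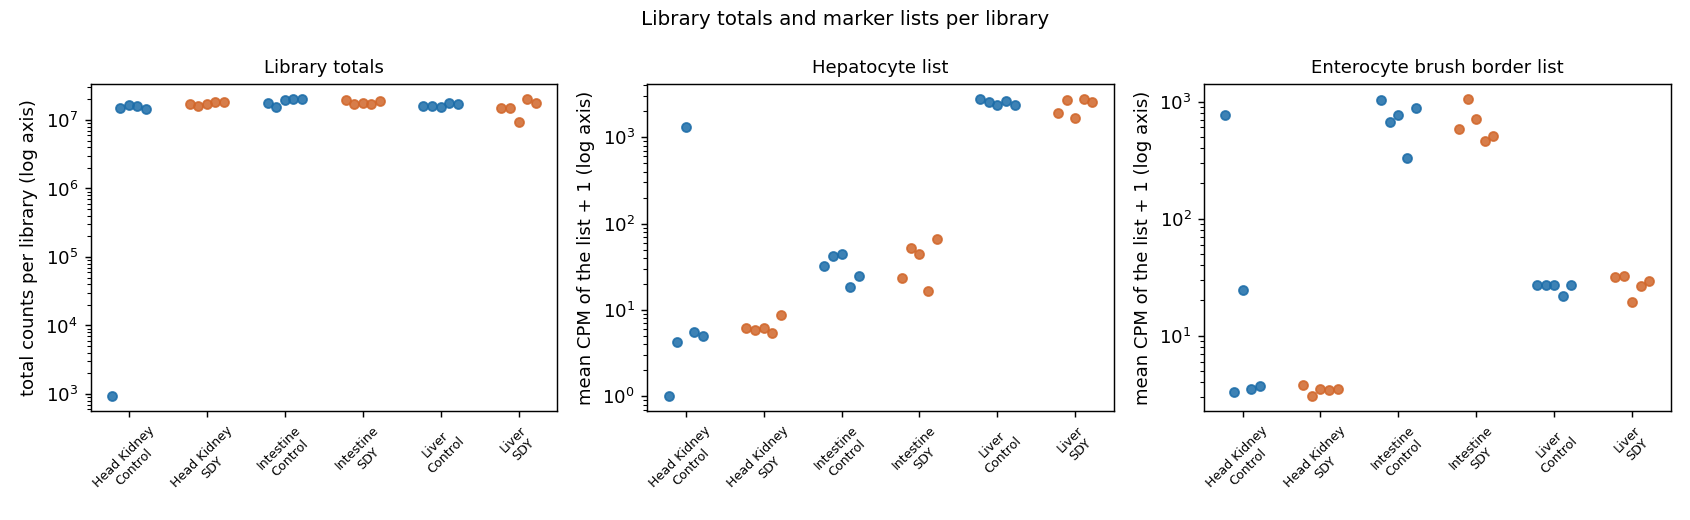
Total counts per library (left), and mean CPM plus 1 of the hepatocyte list (middle) and of the enterocyte brush border list (right), all on log axes, with one point per library by tissue and diet. Head kidney control replicate 1 lies at 926 counts and 765 CPM of the brush border list, and head kidney control replicate 3 at 1310 CPM of the hepatocyte list.

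In head kidney, some but not all of the immune lists rose under SDY relative to other genes. The T cell list had all 11 members above 0, with a median log2 fold change of 0.88, and the interferon response list 10 of 11 members, with a median of 1.01. Antigen presentation lists rose as well, with medians of 0.52 for class I (7 of 7 members above 0) and 0.63 for class II (5 of 6). Adjusted camera p (limma) was 2.64e-05, 0.00204, 0.00542 and 0.0146 in that order; all had adjusted p = 0.834 with an estimated correlation. These 4 lists and the proteasome list stayed past the camera threshold, with the same direction, without control replicates 1 and 3. Their medians were then 0.60, 1.13, 0.61, 0.40 and 0.25, with adjusted p of at least 0.882 with an estimated correlation. Beside these lists, erythroid genes, markers of red blood cells, lay below 0 in 14 of 15 members, with a median of -0.63 (camera adjusted p = 0.0559 by limma) and of -0.59 without the pair (adjusted p = 2.42e-05, and adjusted p = 0.882 with an estimated correlation).

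Among members, irf1, a transcription factor of interferon signalling, had 157 ± 90.1 CPM in controls and 408 ± 204 CPM under SDY (SD, n = 5 each). Its log2 fold change was 1.16 (SE 0.44, edgeR adjusted p = 0.43), and 1.11 (SE 0.41, adjusted p = 0.407) without the pair of control libraries. The RNA sensor gene dhx58 had a log2 fold change of 2.30 (SE 0.89), carried by SDY replicate 2 at 582 CPM against 27.3 to 65.8 CPM in the other SDY libraries; without that library it was 0.58, and without the pair of control libraries 2.28. Without SDY replicate 2, the interferon response list no longer passed. The lymphocyte gene il7r had 28 ± 21.8 and 77.9 ± 29.8 CPM and a log2 fold change of 1.17 (SE 0.41), or 0.88 without the pair. For tbx21, a T helper cell regulator, it was 0.90 (SE 0.35), or 0.64 without the pair. The dendritic cell gene cd83 had 45.5 ± 25.8 and 100 ± 23.2 CPM and a log2 fold change of 0.84 (SE 0.22), or 0.78 without the pair. These control means include the pair. Control replicates 2, 4 and 5 alone had 189 ± 25.5 CPM for irf1, 42.3 ± 11.9 CPM for il7r and 58.5 ± 4.27 CPM for cd83 (SD). Adjusted over the list alone, cd83 was the only member past the threshold in the class II list, and 0 members were in the T cell, interferon and class I lists; without the pair of control libraries, 4 class I members passed. Over all genes, none passed by edgeR.

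The proteasome list had a median of 0.32 (25 of 29 members above 0, adjusted camera p = 0.000273 by limma, and adjusted p = 0.834 with an estimated correlation). The immunoproteasome activator gene psme2 had 113 ± 63.7 and 213 ± 36.2 CPM, and log2 fold changes of 0.66 (SE 0.28) with all libraries and 0.61 (SE 0.15) without the pair. The B cell list rose with a median of 0.47 (13 of 13, camera adjusted p = 0.00204) and the cell cycle list with 0.36 (69 of 70, camera adjusted p = 2.17e-08). Both had adjusted p = 0.834 with an estimated correlation. Without the pair their medians were 0.10 and 0.02, and neither passed. The ribosomal protein list turned. It rose with all libraries (median 0.21, 72 of 72 members, camera adjusted p = 3.86e-05, adjusted p = 0.834 with an estimated correlation). It fell by 0.11 without them (camera adjusted p = 1.14e-06, adjusted p = 0.918 with an estimated correlation).

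Lists that fell in head kidney depended on control replicate 3. Without it alone, none of the 5 passed, while without control replicate 1 alone all 5 did. The renal tubule and oxidative phosphorylation lists also missed without some other single libraries. Cholesterol synthesis had a median of -1.47 (17 of 19 members below 0) and renal tubule genes -2.55 (8 of 8). Fatty acid oxidation had -0.44 (29 of 31), iron, heme and hypoxia genes -0.47 (13 of 16), and oxidative phosphorylation -0.06 (38 of 56). Adjusted camera p (limma) was 0.00787, 0.0498, 1.56e-05, 0.00235 and 0.0465, each with adjusted p = 0.834 with an estimated correlation. Without the pair, the medians were -0.02, 0.00, -0.01, -0.23 and 0.04, and of these lists iron, heme and hypoxia alone still passed (camera adjusted p = 0.0189, adjusted p = 0.882 with an estimated correlation). The renal tubule list averaged 682 CPM in control replicate 1, 67.6 CPM in control replicate 3 and at most 4.83 CPM in the other controls. This list is not particular to kidney, and averaged 346 ± 53.1 CPM in control intestine (SD, n = 5). Its member slc13a3 had 434 CPM in control replicate 3 and at most 3.55 CPM in the other controls, with a log2 fold change of -5.42 (SE 1.63) and of 0.18 without control replicate 3. Ceruloplasmin (cp), a copper protein of plasma, had 2710 CPM in control replicate 3 and at most 1.82 CPM in the other controls. Its log2 fold change was -9.92 (SE 2.71) with all libraries and -0.74 (SE 0.82) without the pair. The sterol gene msmo1 went from -5.04 (SE 1.49) to -0.15 (SE 0.30). Adjusted over the list alone, 10 hepatocyte, 4 renal tubule and 2 iron, heme and hypoxia genes passed as lower under SDY with all libraries, and the hepatocyte list member cps1 as higher; without the pair, 0 passed in each of these lists. The hormone gene epo, a driver of red cell formation, had log2 fold changes of -1.20 (SE 0.35) and -1.01 (SE 0.35). Its span overlaps pop7.

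Interrenal and chromaffin markers, genes of steroid and catecholamine synthesis in tissue embedded in the head kidney, averaged 162 CPM in SDY replicate 3 and 70.2 CPM in SDY replicate 4. Every other head kidney library lay at or below 5.86 CPM. Adjusted over the list alone, 4 of 9 tested members were higher under SDY, among them the steroid genes star (log2 fold change 6.14, SE 1.83) and hsd3b1 (7.04, SE 1.81). Without the pair of control libraries, 7 of 12 members were, with 6.71 (SE 2.39) for star and 6.99 (SE 2.36) for hsd3b1. The list itself missed the camera threshold with all libraries (adjusted p = 0.0967 by limma). Without the pair it passed as higher (adjusted p = 0.0304). So did smooth and skeletal muscle genes (0.0216), while erythroid genes, as above, and macrophage and neutrophil genes (0.0456, median -0.25, against 0.05 with all libraries) passed as lower. All 4 had adjusted p of at least 0.882 with an estimated correlation.

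For single genes in head kidney, edgeR found 0 of 16541 past the threshold (lowest adjusted p = 0.429). At an unadjusted p under 0.05 there were 1722 genes, where 827 would be expected by chance, and DESeq2 called 59, 20 higher and 39 lower. Of those 59, 28 were tested by edgeR, all 28 with the same direction and 27 with an unadjusted p under 0.05. Both tests read the same libraries, so this agreement is not independent support. Named genes with the smallest p were steap2, a metal reductase gene whose span overlaps alg14 (log2 fold change 3.30, SE 0.57), glipr2 (-1.38, SE 0.30) and ldlrad3 (-1.12, SE 0.24). They also included cdk18 (-2.52, SE 0.58) and the chemokine gene ccl17 (1.15, SE 0.27), each with edgeR adjusted p = 0.429. In the same direction without the pair, these were 3.23, -1.53, -0.92, -1.52 and 1.02. Of the alternatives, steap2 gained the threshold in 4 and stayed short of it in 15. By edgeR it passed without SDY replicate 2 (3.55, adjusted p = 0.0197) and with a replicate block (2.80, adjusted p = 0.0471). In the same way, cdk18 and ldlrad3 gained it in 2 each, and glipr2 and ccl17 in 1 each.

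Without control replicates 1 and 3, edgeR called 1 of 17151 genes, LOC115584268 on chromosome 1 (15955789 to 15964928, minus strand, fSpaAur1.1), which has no name in the files. DESeq2 then called 248, 115 higher and 133 lower. LOC115584268 had 214 to 302 counts in control replicates 2, 4 and 5 and 47 in control replicate 3. It had 1 count in the 5 SDY libraries together. The ratio of control to SDY was 1430 (95% counting interval 256 to 56500; edgeR adjusted p = 0.000262). In intestine it had 0 to 13 counts in control libraries and 0 to 77 in SDY libraries.

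In intestine, the interferon response list rose under SDY, with all 11 members above 0 and a median log2 fold change of 0.73. This call and those of the next 9 lists were by camera, and each had adjusted p = 0.834 with an estimated correlation. The proteasome list rose with a median of 0.43 (28 of 29 members), oxidative phosphorylation with 0.23 (49 of 56), and fatty acid oxidation with 0.21 (24 of 33). Cell cycle genes rose with a median of 0.20 (63 of 70), and class I antigen presentation genes with 0.33 (7 of 7). Connective and vascular lists fell. Extracellular matrix and fibroblast genes had a median of -0.27 (17 of 20 below 0), adipose and endothelial genes -0.31 (15 of 18), and smooth and skeletal muscle genes -0.30 (11 of 12). Ribosomal proteins had a median of -0.15 (72 of 72).

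Adjusted camera p (limma) for the lists that rose was 3.83e-07, 7.62e-09, 8.27e-10, 0.000273, 1.57e-10 and 0.0253 in the order given. For those that fell it was 3.08e-05, 0.00787, 0.015 and 5.42e-06. Among members, cmpk2, an interferon-induced kinase gene, had 12.1 ± 7.73 CPM in controls and 28.6 ± 13.6 CPM under SDY (SD, n = 5 each; log2 fold change 1.24, SE 0.48). The RNA sensor gene ifih1 had 73.1 ± 22.9 and 122 ± 33.2 CPM (0.74, SE 0.25). The mitochondrial genes hadh (0.47, SE 0.19) and etfa (0.34, SE 0.14) had smaller values, and etfa overlaps tmem266. The pericyte receptor gene pdgfrb had 32.8 ± 3.3 and 22.8 ± 2.53 CPM (log2 fold change -0.53, SE 0.12). The smooth muscle regulator myocd had -0.53 (SE 0.21), and the vessel gene cdh5 -0.31 (SE 0.14). Without control replicate 2, myocd had -0.33 and lmod1, of the same list, -0.25 in place of -0.49, and the muscle, class I and ribosomal lists no longer passed. The muscle list also missed without SDY replicate 1 or 3, the adipose and endothelial list without control replicate 5 or SDY replicate 1, and the class I list without control replicate 1 or 5 or SDY replicate 1 or 4. Adjusted over the list alone, pdgfrb was the only member past the threshold in these 10 lists (adjusted p = 0.0209 by edgeR), and none passed over all genes.

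Cell cycle genes also set control replicate 4 apart, at 45.8 CPM against 4.12 to 14.7 CPM in the other control intestines. The same library had a fitted head kidney share of 0.172. The interferon list averaged 91.5 CPM in SDY replicate 2 and 142 to 159 CPM in the other SDY libraries. The exocrine pancreas list averaged 223 CPM in control replicate 2 against at most 20 CPM in the other controls.

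For single genes in intestine, edgeR found 0 of 18221 past the threshold (lowest adjusted p = 0.739), 1175 at an unadjusted p under 0.05 (911 expected by chance), and DESeq2 called 55, 31 higher and 24 lower. Of those 55, 46 were tested by edgeR, all 46 with the same direction and an unadjusted p under 0.05, again on the same libraries. Named genes with the smallest p were abhd4, a lipid hydrolase gene (9.8 ± 1.59 and 16.8 ± 2.19 CPM, log2 fold change 0.78, SE 0.15), and fam189a1 (-2.01, SE 0.42). Others were nfatc4 (-0.74, SE 0.15), sost, a Wnt antagonist gene (-0.84, SE 0.18), and pdgfrb, each with edgeR adjusted p = 0.739.

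In liver, immediate early genes, which respond within minutes to hours to stimuli, rose under SDY as a list (camera adjusted p = 8.1e-06 by limma, adjusted p = 0.527 with an estimated correlation, and 0.111 by fry). Of 18 members, 17 were above 0, with a median log2 fold change of 0.49 and quartiles of 0.09 and 1.52. The stress transcription factor atf3 had 4.35 ± 1.52 CPM in controls and 39.4 ± 18.2 CPM under SDY (SD, n = 5 each; log2 fold change 3.18, SE 0.42). The cytokine signalling inhibitor socs3 had 8.92 ± 2.21 and 68.3 ± 38.1 CPM (2.94, SE 0.47). Adjusted over the list alone, 7 members passed as higher by edgeR, namely atf3, socs3, fosl2, gadd45b, fosl1, myc and ier2, and 0 passed over all genes.

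**Figure D2:**
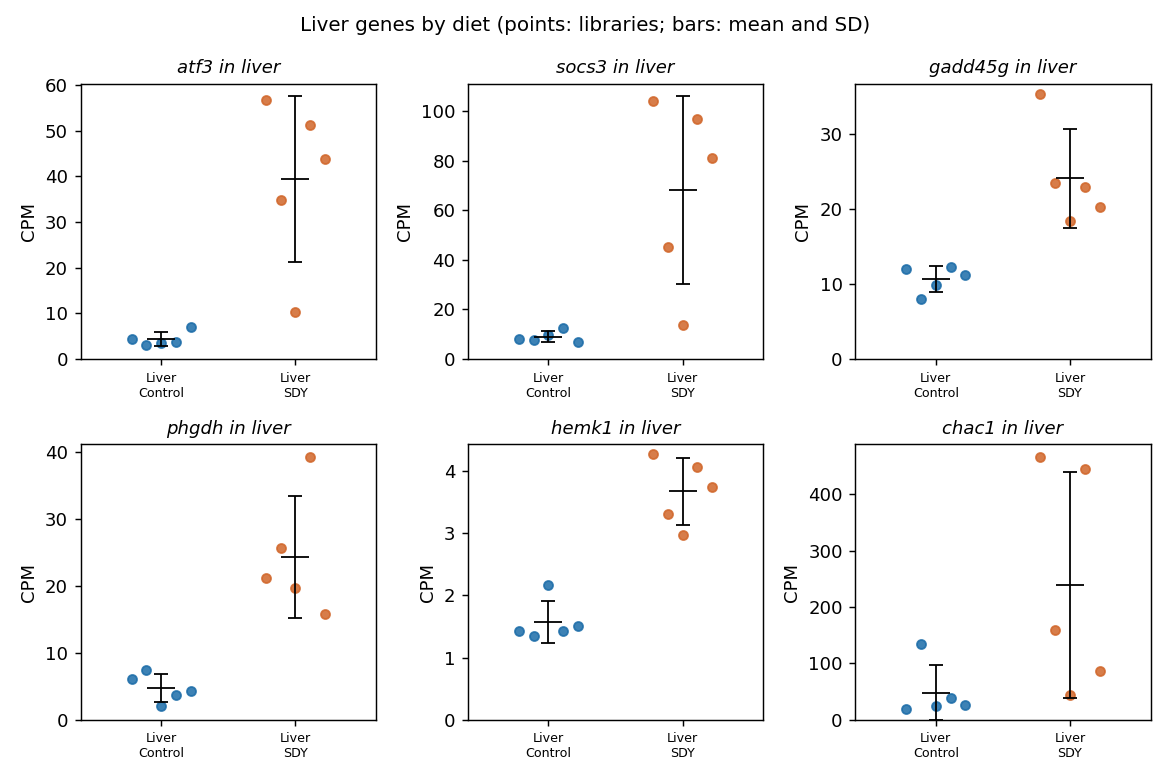
CPM of 6 genes in liver by diet, with one point per library (n = 5 per diet) and bars for the mean and SD on linear axes. For atf3, socs3, gadd45g, phgdh and hemk1, picked for the smallest p, all SDY libraries lie above all control libraries, and for atf3 SDY replicate 3 is the lowest SDY library at 10.3 CPM.

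The proteasome list rose in liver with a median of 0.50 (28 of 29 members above 0), and 18 members had an unadjusted p under 0.05 by edgeR. Endoplasmic reticulum (ER) stress genes rose with a median of 0.26 (29 of 37), oxidative phosphorylation with 0.15 (43 of 56), and cell cycle genes with 0.25 (45 of 55). Circadian clock genes fell, with a median of -0.32 (7 of 8 below 0). Adjusted camera p (limma) was 5.81e-10, 0.00787, 0.00687, 0.0456 and 0.0128, each with adjusted p = 0.834 with an estimated correlation. Without control replicate 2, the clock, oxidative phosphorylation and cell cycle lists no longer passed, and each also missed without some other single libraries. The ER stress list missed without SDY replicate 4. The proteasome list passed whichever library was left out. Adjusted over the list alone, atf3 in the ER stress list and bhlhe41 in the clock list passed, and 0 members in the other 3 lists. The glutathione-degrading gene chac1, of the ER stress list, had 48.4 ± 48.6 and 240 ± 200 CPM (log2 fold change 2.31, SE 0.76). The clock repressor bhlhe41 had 8.78 ± 1.85 and 4.64 ± 1.75 CPM (-0.93, SE 0.27), and psmc4 of the proteasome 31.8 ± 8.67 and 58.2 ± 26 CPM (0.87, SE 0.30).

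Outside these lists, phgdh, the first enzyme of serine synthesis, had 4.68 ± 2.1 CPM in controls and 24.3 ± 9.08 CPM under SDY (log2 fold change 2.37, SE 0.35). It passed when adjusted over the list alone in the amino acid list (adjusted p = 0.00158 by edgeR), as did the urea cycle gene otc (1.88, SE 0.45, adjusted p = 0.0484). That list had 29 of 59 members above 0 and missed the camera threshold. The growth arrest gene gadd45g had 10.6 ± 1.74 and 24 ± 6.61 CPM (1.18, SE 0.19), and the methyltransferase gene hemk1 1.57 ± 0.339 and 3.67 ± 0.538 CPM (1.22, SE 0.20). In each of these 3 genes, and in atf3 and socs3, the 5 SDY libraries lay above the 5 controls. All were picked as the named genes with the smallest p, so this separation comes in part from the choice.

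Over all genes in liver, edgeR found 0 of 15010 past the threshold (lowest adjusted p = 0.165, for atf3 on chromosome 22, 8388165 to 8392974, fSpaAur1.1). The other 4 named genes, phgdh, gadd45g, hemk1 and socs3, had edgeR adjusted p = 0.18. At an unadjusted p under 0.05 there were 1594 genes (750 expected by chance), and DESeq2 called 103, 66 higher and 37 lower. Of those, 91 were tested by edgeR, and all 91 had the same direction and an unadjusted p under 0.05. As in the other tissues, the shared libraries make this agreement no independent support. Without SDY replicate 3, edgeR called 17 genes, 12 higher and 5 lower, including atf3 (adjusted p = 0.00086), socs3 (0.00154) and fosl2 (0.0106). In fits that left it out, SDY replicate 3 lay near the control end of a scale from controls to SDY. Its median position was 0.109, against 0.622 to 0.91 for the other SDY libraries. Leaving out such a library widens the difference between the diets, so the 17 calls are no independent support.

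**Figure D3:**
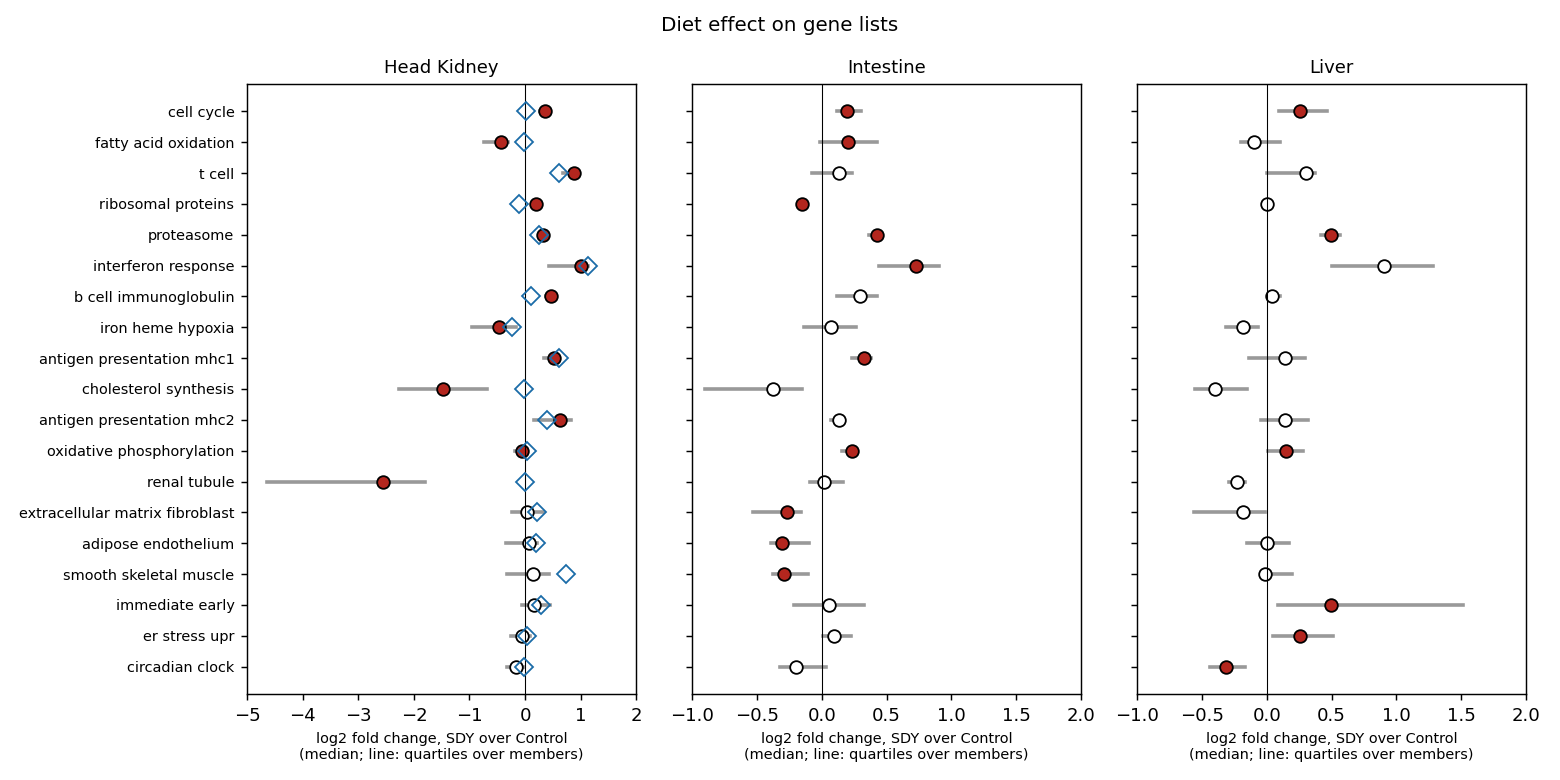
Median log2 fold change, SDY over control, of gene lists in the 3 tissues, with lines for the quartiles over members. Filled circles passed camera with a preset correlation, open circles did not, and diamonds in the head kidney panel leave out control replicates 1 and 3; cholesterol synthesis moves from -1.47 to -0.02.

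Whether the diet effect differed between tissues was tested in one edgeR fit. Between intestine and liver, 4 of 19736 genes passed, all with a higher effect in liver. They were fosl2 (difference, intestine minus liver, -2.70, SE 0.49), socs3 (-3.34, SE 0.60), trib1, a pseudokinase gene (-2.87, SE 0.52), and hemk1 (-1.61, SE 0.28), each with edgeR adjusted p = 0.0436. For fosl2 the log2 fold change was -0.01 in intestine and 2.68 in liver. Without head kidney control replicates 1 and 3, fosl2 and hemk1 kept adjusted p = 0.024, while socs3 and trib1 had 0.0565 and 0.0612. At an unadjusted p under 0.05 there were 735 genes (987 expected by chance), and 35 were called by DESeq2. With RLE size factors, without a filter, or with the 20 libraries of both tissues alone, edgeR called 0.

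Between head kidney and intestine 202 genes differed, 13 higher and 189 lower in head kidney, and between head kidney and liver 470, 15 higher and 455 lower. Against intestine, the named genes with the smallest p included cdh17 (-10.25, SE 1.92), a cadherin gene of the renal tubule list that is also high in intestine. The others were the fructose kinase gene khk (-9.54, SE 1.84), a1cf (-9.65, SE 1.93), acmsd (-9.72, SE 1.93) and the liver transcription factor creb3l3 (-8.73, SE 1.75). All 5 had edgeR adjusted p = 0.0343. Their head kidney controls include the libraries with intestine-type and liver-type counts. Without them, 1 gene differed between head kidney and intestine and 2 between head kidney and liver; 1 of the 202 and 1 of the 470 were kept. With the 20 libraries of each pair of tissues alone, edgeR called 0 for both, against 637 and 783 by DESeq2 with all libraries. Without head kidney control replicates 1 and 3, the edgeR difference from intestine was -1.06 (SE 0.62) for cdh17 and -0.25 (SE 0.68) for a1cf. Without head kidney control replicate 3 alone, that of cdh17 was -1.86. The difference of fosl2 between head kidney and liver was kept, at -2.78 (SE 0.50, edgeR adjusted p = 0.0221) with all libraries and -3.08 (SE 0.46, adjusted p = 0.00936) without the pair.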

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

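The tests of liver RNA, of a wrong label and of the control diet for head kidney control replicate 3, and those of intestine reads and of low depth for control replicate 1, were chosen after the result was seen. Of 190 groups of 5 libraries examined by Dixon's criterion, 36 had a library far from the rest, where chance flags about 1 in 20 groups, or 9.5. Head kidney controls held 20 of them, 12 in replicate 1 and 8 in replicate 3, and 16 lay elsewhere. The groups share libraries and genes, so they are not independent.

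Head kidney control replicate 3 stood far from the other controls in the hepatocyte list (1310 CPM, others at most 4.52 CPM) and the exocrine pancreas list (228 CPM, others at most 1.39 CPM). It also did so in cp (2710 CPM), msmo1 (698 CPM), sc5d (311 CPM), slc13a3 (434 CPM), decr2 (125 CPM) and nphs1 (11.8 CPM). Liver RNA or tissue mixed into the sample is a candidate explanation: the 671 genes at least 20 times higher in liver lay at a median of 0.566 of their liver level (quartiles 0.425 and 0.709), against 0.000856 to 0.00259 in the other head kidney libraries. The 982 genes at least 20 times higher in head kidney lay at 0.218 of their head kidney level (quartiles 0.161 and 0.292), near the lower edge of the range set for a mixture. This is below the head kidney share of 0.469 in the mixture fit, which allowed only 3 tissues. Head kidney and liver in the fitted shares therefore do not account for the library, and those shares are uncertain. That 0.218 argues against a wrong label of a pure liver sample, which would hold these genes at no more than 1 in 20. The control diet is argued against by the 4.52 CPM of the hepatocyte list in the other controls. Renal genes that are low in liver also stood high in CPM of the plain library total, such as cdh16 at 53.8 CPM (other head kidney libraries 0.0073 and liver 0.49 CPM on average), pax8 at 12.7 CPM and lrp2 at 183 CPM; their source was not tested.

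Head kidney control replicate 1 stood far from the other controls in its total of 926 counts, in the brush border list (765 CPM) and in the renal tubule list (682 CPM). It did so as well in the interferon list (196 CPM), the immediate early list (0 CPM), erap2 (89.3 CPM) and rps3 (179 CPM), and at 0 CPM in cd83, irf1, psmb2, psme2 and rfxank. At 926 counts in all, each value in that last group rests on a few reads or none, and depth alone can give a 0. List values are relative to the plain total, and gene values are TMM-scaled, with a factor of 16.3 for this library. Reads of an intestine sample are a candidate explanation, with a fitted intestine share whose lower 95% bootstrap bound was 0.998. Low depth alone is argued against by 2 counts on 209 genes at least 20 times higher in head kidney than in intestine, where 96.7 would be expected (Poisson interval 78 to 116). On 950 intestine genes it had 356 counts, where 289 would be expected from an intestine profile (256 to 323). No biological explanation was tested, and how the reads came into the library stays open.

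In other head kidney libraries, SDY replicate 2 was far from the rest in the interferon list (318 CPM), dhx58 (582 CPM) and erap2 (81.9 CPM). SDY replicate 1 was so in the exocrine pancreas list (3.48 CPM) and nphs1 (1.7 CPM), and SDY replicate 5 in the hepatocyte list (7.76 CPM). In intestine, control replicate 4 stood apart in the cell cycle list (45.8 CPM) and sost (12.4 CPM), and control replicate 2 in the exocrine pancreas list (223 CPM). SDY replicate 1 did so in ccne1 (4.21 CPM) and etfa (109 CPM), and SDY replicate 2 in the interferon list (91.5 CPM). In liver, control replicate 4 stood apart in the brush border list (20.7 CPM) and the interrenal list (2.75 CPM), control replicate 2 in chac1 (134 CPM), and control replicate 3 in hemk1 (2.17 CPM).

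The diet effect differed between tissues by edgeR in 202 genes for head kidney and intestine, 470 for head kidney and liver, and 4 for intestine and liver. Against intestine, the head kidney differences were -10.25 for cdh17, -9.54 for khk, -9.72 for acmsd, -9.65 for a1cf and -8.73 for creb3l3. Against liver they were -2.78 for fosl2, -9.69 for cdh17, -9.23 for khk, -9.52 for a1cf and -8.59 for creb3l3. For intestine against liver they were -1.61 for hemk1, -2.87 for trib1, -3.34 for socs3 and -2.70 for fosl2. Without head kidney control replicates 1 and 3 the counts were 1, 2 and 2. Among 60 regroupings within tissues with the real one included, 28, 24 and 3 gave as many genes, with at most 3355, 985 and 1681 in the others, so chance cannot be excluded. Regroupings that called several times the real count point to a structure of the samples.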

How the results depend on the processing

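The fits without head kidney control replicates 1 and 3, those of 28 libraries and the averaged effect were chosen after seeing the data. Of 83 results for named genes, 78 kept their direction under every alternative run. Over their 1756 alternatives, 1456 kept direction and side of the threshold, 234 lost the threshold, 45 gained it and 21 reversed. Named genes within a tissue had not passed, so they could not lose the threshold, and all 234 losses fell on differences between tissues. Genes that passed for head kidney and intestine each lost it in 17 alternatives and kept it in 19. For head kidney and liver they lost it in 4 to 6 and kept it in 30 to 32. For intestine and liver they lost it in 29 to 31 and kept it in 5 to 7. The cause was not tested except where stated. RLE size factors moved the median log2 fold change by 0.059 in head kidney, 0.013 in intestine and 0.01 in liver, and gave 0 genes by edgeR in each. At the depth and spread here, edgeR recovered 16% of simulated 2-fold changes in head kidney, 23% in intestine and 43% in liver, so most changes of that size would be missed; smaller ones were not simulated.

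For genes past the threshold in head kidney, where edgeR had 0, DESeq2 gave 59, no filter 1 (LOC115584268) and one fit of all 30 libraries 1445. Without control replicates 1 and 3, edgeR gave 1, DESeq2 248 and one fit of 28 libraries 1. In intestine DESeq2 gave 55. In liver DESeq2 gave 103, one fit of 30 libraries 14 and one of 28 libraries 27. Leaving out 1 library gave 0 to 2 genes in head kidney, 1 without control replicate 1, SDY replicate 1 or SDY replicate 3, and 2 without SDY replicate 2 or 4. It gave 0 to 3 in intestine, 1 without SDY replicate 1 and 3 without SDY replicate 2. In liver it gave 0 to 17, 1 without control replicate 4 and 17 without SDY replicate 3.

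For the difference between head kidney and intestine (202 genes), DESeq2 gave 637, the 20 libraries alone 0, and the fit without head kidney control replicates 1 and 3 gave 1. For head kidney and liver (470) these were 783, 0 and 2, and for intestine and liver (4) they were 35, 0 and 2, with 0 under RLE and 0 without a filter. Leaving out 1 library gave 0 to 640, 0 to 839 and 0 to 7 genes. The first was 640 without head kidney control replicate 4 or 5, 621 without replicate 2, 126 without replicate 1 and 1 without replicate 3. It was 0 without head kidney SDY replicates 1 to 4 or any intestine control, 6 without head kidney SDY replicate 5, and 1 without intestine SDY replicate 2, 3 or 5. It was 123 to 132 without liver control replicate 1, 3 or 5 or liver SDY replicates 2 to 5. The second was 832 to 839 without head kidney control replicate 2, 4 or 5, 2 without replicate 3, and 0 without SDY replicate 2 or 3. It was 228 to 302 without head kidney SDY replicate 4 or 5 or liver control replicate 1, 2, 3 or 5. The third was 7 without liver SDY replicate 3, 2 without intestine or liver control replicate 3, 1 without intestine SDY replicate 4 or liver control replicate 4, and 0 without any other library except head kidney control replicate 3 and liver SDY replicate 2.

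For gene lists, an estimated correlation gave 0 in head kidney, 0 in intestine and 0 in liver, as did fry, in place of 13, 10 and 6. Leaving out 1 library gave 9 to 17 in head kidney, 7 to 14 in intestine and 3 to 8 in liver, where the 3 came without control replicate 2. In liver it was 4 without SDY replicate 2.

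The log2 fold changes of decr2, ndufb3 and slc13a3 in head kidney turned to 0.091, 0.062 and 0.080 by voom with quality weights. Leaving out 1 library gave -2.34 to 0.093, -0.82 to 0.081 and -5.81 to 0.184, each time with the highest without control replicate 3. Without control replicates 1 and 3 they were 0.090, 0.098 and 0.181 by edgeR, 0.082, 0.090 and 0.170 by DESeq2, and 0.084, 0.096 and 0.180 in the fit of 28 libraries. For rps29 and rps3 they turned to -0.054 and -0.029, -0.063 and -0.037, and -0.057 and -0.032 in those 3 fits.

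A replicate block gave 3 genes in head kidney by edgeR, 0 in intestine and 0 in liver, and 0 genes for each of the 3 differences between tissues. Residuals of same-numbered libraries correlated by over 0.1 in 4 of 15 pairs across diets and 6 of 30 pairs across tissues. The correlations ran from -0.146 to 0.544 across diets and from -0.248 to 0.273 across tissues. Pairs with different numbers were not set beside them, so these values cannot show whether same-numbered libraries were paired.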

Other observations

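The tests of the averaged effect, of the label and of the exchange of liver libraries, of shared handling, of ATF4 targets in other tissues and by permutation, and the splits of 8 head kidney libraries at unadjusted p were chosen after results were seen. Averaged over the 3 tissues, without head kidney control replicates 1 and 3, 5 of 20296 genes passed by edgeR, 2 higher and 3 lower under SDY, and none has a name in the files. LOC115588458 on chromosome 9 (34455555 to 34468151, plus strand) had an averaged log2 fold change of 2.37 (SE 0.39, adjusted p = 0.0291). Relative to the plain library total, it had 0.87 to 1.98 CPM in control livers and 3.07 to 27.6 CPM under SDY. Its values overlapped between diets in the other tissues. It had 3.38 to 8.54 and 6.4 to 126 CPM in head kidney, without control replicates 1 and 3, and 2.59 to 7.97 and 5.24 to 17.7 CPM in intestine. LOC115588457, at 1.27 (SE 0.23), overlaps it on the same strand, so reads may have been counted for both; its adjusted p was 0.0444 by edgeR, and with all 30 libraries 564 genes passed. LOC115581573 (-1.20, SE 0.21), LOC115589080 (-1.30, SE 0.22) and LOC115572578 (-1.22, SE 0.22) were lower in each tissue. On the same scale, LOC115581573 in intestine had 4.37 to 9.46 CPM in controls and 2.43 to 3.77 CPM under SDY. In head kidney, without control replicates 1 and 3, it overlapped, with 221 to 353 and 69.6 to 240 CPM. Of 60 regroupings, 3 gave as many genes with the real one included, at most 10 in the others against 5, so chance cannot be excluded. The fit and the regroupings took libraries of different tissues as independent, and the SE and adjusted p rest on this. If the tissues came from the same fish, a trait of a few fish could pass as a diet effect.

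Genes of cholesterol synthesis lay below 0 in 24 of 25 members in intestine (median log2 fold change -0.38) and in 21 of 24 in liver (median -0.40). Neither passed camera (adjusted p = 0.208 and 0.947 by limma), and in liver camera's direction was up while the median and mean were below 0. In head kidney without control replicates 1 and 3 the median was -0.02. The interferon response list had 10 of 11 members above 0 in liver, with a median of 0.90 (adjusted p = 0.0846 by camera in limma). The antigen presentation gene nlrc5 was lower in liver when adjusted over the list alone (-1.80, SE 0.54, adjusted p = 0.0469 by edgeR), and cd83 was higher (0.84, SE 0.25, adjusted p = 0.0349).

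In liver, immediate early genes rose as a list by camera (adjusted p = 0.527 with an estimated correlation and 0.111 by fry, in limma), and phgdh and otc passed as higher within the amino acid list, which itself missed the threshold; SDY replicate 3 lay near the controls. In fits that left it out, its median position on the 50 genes with the smallest p was 0.109 on a scale from controls (0) to SDY (1), with a range of 0.055 to 0.191, and the other SDY libraries lay at 0.622 to 0.91. A wrong label, or an exchange with control replicate 2, which lay at 0.649 (upper quartile 0.816) when both were left out, is a candidate explanation; a first version of the test on 17 genes gave 0.138. Held-out controls ranged widely, however, with control replicate 4 at 0.485 (0.409 to 0.564, and an upper quartile of 0.878 when it and SDY replicate 3 were left out), and phgdh, hemk1 and gadd45g follow the labels in SDY replicate 3 and control replicate 2 (hemk1 at 2.96 and 1.34 CPM), though they were picked for their difference; differences between fish stay open, and no library was relabelled. Handling that reached every tissue alike was tested by the difference between liver and intestine in the immediate early list. Its median was 0.80, with 15 of 18 members above 0 (fry p = 0.000203 in limma, exact two-sided permutation p = 0.0046 over 63504 regroupings). This goes against an equal fold change in both tissues, but the list was taken up because it had risen in liver. It also averaged 43.1 CPM in control intestine and 8.62 CPM in control liver, so an equal stimulus need not give an equal fold change. Shared handling therefore stays open. The head kidney median without the doubted pair was 0.29 (camera adjusted p = 0.075), so handling that reached some tissues and not the intestine stays open too.

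A hypothesis was that the liver genes are part of the amino acid response through ATF4, a transcription factor that raises amino acid transporters and tRNA synthetases. The test on 28 targets was written before its own result, but ER stress genes had been seen, and 10 of the 28 are in the fixed lists. Targets noted by then as higher, chac1 among them, were left out. The target wars1 stayed in, although DESeq2 also called it higher in liver (log2 fold change 1.31, adjusted p = 0.0498). The list was thus not free of genes called in these data. All 28 targets lay above 0 in liver (median 0.67, fry p = 0.0104 in limma; camera p = 0.0273 with an estimated correlation), and 17 passed when adjusted over the list alone and 0 over all genes by edgeR. Examples are asns (1.33, SE 0.39), wars1 (1.30, SE 0.36) and yars1 (1.08, SE 0.33). An exact two-sided permutation test of the list mean over 252 splits gave p = 0.0159 in liver (adjusted p = 0.0477 over 3 tissues), 0.571 in intestine, and 0.857 in head kidney over the 56 splits of 8 libraries. The values are consistent with such a response, which may also differ between fish for other reasons, since control replicate 2 had a list mean of 0.15 and SDY replicate 3 of -0.114.

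Other splits of the 10 libraries of a tissue show what chance gives. The edgeR counts of 0 test nothing, since all 100 splits of each tissue reach 0; the highest other counts were 2 in head kidney, 2605 in intestine and 205 in liver. In head kidney, 4 of 30 splits gave the 59 of DESeq2 (at most 146), and 59 of 100 gave the 13 lists (at most 18). For the 1722 genes at an unadjusted p under 0.05, 3 of 100 splits gave as many (at most 2392), a share under 0.05, but the draw mixes splits that part control replicates 1 and 3 with splits that do not. That pair fell on the same side, as in the real split, in 43 of the other splits, with a median of 1168 and 2 as large, and on opposite sides in 56, with none as large and at most 1592. Chance is therefore not excluded for these counts, and the excess does not separate diet from that pair of libraries.

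Without that pair, 10 of 56 splits gave at least 1 gene by edgeR (at most 600), 3 of 56 gave the 2011 genes at an unadjusted p under 0.05 (at most 3556), 4 of 30 gave the 248 of DESeq2 (at most 1991) and 10 of 56 gave the 11 lists (at most 14). In intestine, 21 of 100 splits gave the 1175 at an unadjusted p under 0.05 (at most 6233), 7 of 30 gave the 55 of DESeq2 (at most 4285) and 44 of 100 gave the 10 lists (at most 15). In liver, 6 of 100 splits gave the 1594 at an unadjusted p under 0.05 (at most 2790), 3 of 30 gave the 103 of DESeq2 (at most 209) and 89 of 100 gave the 6 lists (at most 17). Chance cannot be excluded for any of these. The split with 2605 genes parts intestine controls 1, 2 and 5 and SDY 2 and 3 from the rest, the one with 600 parts head kidney SDY 2, 3 and 4, and the one with 205 sets liver SDY 3 with controls and control 2 with SDY; counts so far above the real ones point to a structure of the samples.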
